A study of Mus musculus with 24 samples.

How the data were processed

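Peak lists of H3K27ac chromatin immunoprecipitation and sequencing from mouse limb buds were compared between 4 groups with 1 library each: control E11.5, Sox9null E11.5, control E12.5 and Sox9cKO E12.5, as the sample titles give them. The deposited lists give for each peak its position and a score, and no header says what the score is. Its values run from 50.01 to 3233.06 with many ties near the top, so it was taken as the authors' own and used only to rank and filter peaks within a list. Per the submitters' processing notes the genome build was mm10, and CASAVA 1.8 and deepTools were used. The peak names in the lists name MACS as the caller. Its version and settings, the aligner, and whether an input library was used are not given in the sources used here. Each sample has 1 list, so peaks were not called on pooled samples. The depth in reads is unknown, and the number, width and covered length of peaks move with it. The deposited names of 2 lists, those of the Sox9-deficient samples, disagree with the sample titles, so the titles were taken for the main values and the exchanged assignment as an alternative.

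Genes were taken from a RefSeq table of the same assembly, with 21883 protein-coding genes on the autosomes, X and Y. It gives no strand, so the planned promoter state became a peak within 1000 bp of either gene end. For each gene the bp covered by peaks over the gene body plus 20 kb on each side was summed. Peaks of 2 lists were called overlapping at 1 bp, with Wilson 95% intervals that cover counting error only, and set against the same list shifted by 1, 2, 3, 4 and 5 Mb. Regions were the union of the 4 lists, and were counted when marked in both lists of a pair and in neither other list. For 14 gene lists the median difference in covered kb was placed among 10000 random gene lists of the same size, matched in 10 bins on the mean coverage of the lists compared, and reported as a percentile that describes these libraries. The gene lists were cartilage matrix, chondrogenic regulators, condensation and adhesion, limb patterning, BMP and joint, growth plate, skeletal muscle, endothelium, erythroid and macrophage, ectoderm, tendon and connective tissue, nerve and glia, housekeeping, and inactive tissues. All listed symbols were matched, 1 of them (Ctgf) under its present symbol Ccn2.

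The gene lists, comparisons, alternatives and the rule for naming genes were fixed before the data were examined. The rule names Sox9 in every list, and from each gene list up to 4 members whose gene-end state differs, the 2 largest gains and the 2 largest losses. It also names the 10 largest gains and 10 largest losses over all genes where both controls lie on the same side of both deficient lists, and the 5 highest-scored peaks found in 1 list alone. Members of the cartilage matrix and regulator lists may all be named. A few genes that the rule names are not reported here. Other names are said to be chosen after their values were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The scripts were tested on simulated data for the comparison of both deficient with both control lists. All of 200 planted regions were recovered, and 80 regions were counted on the side where none was planted and peaks were only dropped at random. Full recovery was fixed in advance, because planted peaks were always kept in the control copies and always removed from the deficient copies. It checks only that the counting works. Of 200 simulated lists of 30 genes, 99.5% were called low after a 10% reduction of covered length, and 6.0% were called either way with no reduction. The region check used copies of the E11.5 control list, and simulated genes were drawn independently from those above a coverage floor. The real lists differ more and hold poorly covered and clustered genes, so these rates need not carry over to them.

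The alternatives were the upper 50% of each list by score, the same number of top peaks from each list, autosomes alone, the exchanged lists, other overlap, merging and gene-end rules, gene bodies plus 5 or 100 kb, and covered length scaled to the total of each list. Leaving out 1 of the 4 lists in turn, and the stricter lists at Sox9, were added after the data were seen. A SOX motif search was planned but needs the genome sequence, which was not used here. The 20 libraries of other marks and inputs were not analysed here.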

Results

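H3K27ac, a histone acetylation found at active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in limb buds of mouse embryos at embryonic day E11.5 and E12.5. Control embryos were set against embryos deficient in Sox9, the transcription factor required for cartilage formation, at the stages when limb mesenchyme condenses and starts to express cartilage genes. The question was which acetylated chromatin of the early cartilage programme depends on Sox9. Of the 24 samples of the series, which cover 5 histone marks and 4 input libraries, the 4 H3K27ac libraries with a peak list were used, and 20 libraries were not analysed here. Each group (control E11.5, Sox9null E11.5, control E12.5, Sox9cKO E12.5) had 1 library. There were no replicates, no difference between conditions was tested, and the values describe these libraries. Each stage had its own kind of Sox9 deficiency (Sox9null or Sox9cKO), so stage and kind of deficiency cannot be told apart among the deficient lists.

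The control list held 36045 peaks over 52.0 Mb at E11.5 and 32821 peaks over 66.7 Mb at E12.5. The list labelled Sox9null held 28419 peaks over 59.7 Mb, and the list labelled Sox9cKO held 36937 peaks over 60.4 Mb. Median peak widths were 1141 bp and 1707 bp in the E11.5 and E12.5 controls, 1778 bp in the list labelled Sox9null and 1332 bp in the list labelled Sox9cKO. The deposited names of the 2 Sox9-deficient lists are exchanged relative to the titles of their samples. Groups were taken from the titles, each of these lists is called by its label, and the comparisons that depend on the assignment are given both ways. Values of single genes are the kb covered by peaks over the gene body plus 20 kb on each side, in the order control E11.5, control E12.5, labelled Sox9null, labelled Sox9cKO unless stated.

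Sox9 itself (chromosome 11, 112782210 to 112787757, mm10, 5548 bp) was marked over 96.6% of its length in the E11.5 control and 81.3% in the E12.5 control, against 55.8% in the list labelled Sox9null and 54.3% in the list labelled Sox9cKO. In both Sox9-deficient lists a peak covered the left part of the gene and another peak its right end, and the part between them was free of peaks over 2453 bp (112784128 to 112786580) in the list labelled Sox9null and 2533 bp (112783852 to 112786384) in the list labelled Sox9cKO. The longest uncovered stretch within the gene was 188 bp in the E11.5 control and 1037 bp in the E12.5 control, the latter at the right end of the gene. In the large gene desert between Gm11677 and Sox9, which holds long-range Sox9 enhancers, peaks covered 19.5 kb in the E11.5 control, 61.5 kb in the E12.5 control, 56.7 kb in the list labelled Sox9null and 32.9 kb in the list labelled Sox9cKO. Between Sox9 and Slc39a11 the covered lengths were 23.4, 27.4, 26.9 and 31.5 kb. With only the upper 50% of each list by score, 34.6% of the gene was covered in the list labelled Sox9null.

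**Figure D1:**
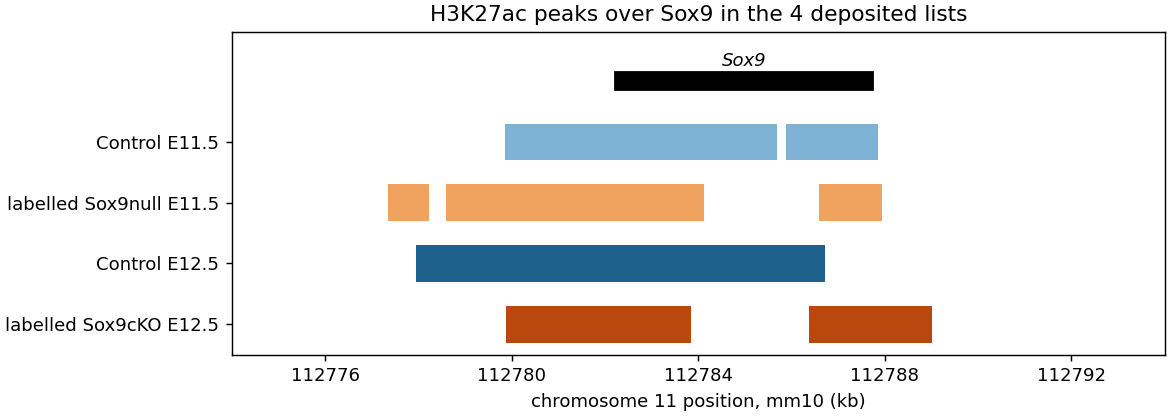
H3K27ac peaks (coloured boxes, one line per list) over Sox9 (black box) along chromosome 11 in kb, mm10. Both Sox9-deficient lists leave the middle of the gene without a peak, over 2453 and 2533 bp, where both controls have peaks over most of that stretch.

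Cartilage matrix genes and chondrogenic transcription factors were covered by less H3K27ac on the mean of the Sox9-deficient lists than on the mean of the controls. For the cartilage genes the difference rested on the E12.5 control, and for the transcription factors it was weaker without that control. This comparison of both deficient with both control lists addresses which acetylation goes with the loss of Sox9, and does not depend on how the deficient lists are assigned. Of 30 cartilage matrix genes, 20 were covered by less and 9 by more on the mean of the lists, with a median difference of -0.416 kb. Of 10000 random gene lists matched on covered length, 0 had a median as low, but without the E12.5 control the median was 0.073 kb (percentile 32.4). Against the E11.5 control 15 genes were covered by more and 13 by less in each deficient list, on unscaled covered length. Wwp2, which hosts a cartilage microRNA, had 27.1 and 55.9 kb in the controls and 33.5 and 22.5 kb in the deficient lists. Papss2, which makes the sulphate donor for proteoglycans, had 1.11 and 10.3 kb in the controls and 1.33 and 1.32 kb in the deficient lists. In 7 genes both deficient values lay below both controls, among them Cspg4 (6.18, 11.3, 3.57 and 5.24 kb), the matrilin gene Matn4 (1.90, 6.46, 0 and 1.68 kb), Ucma (0.716, 1.59, 0 and 0 kb) and Chad (2.65, 3.04, 1.49 and 1.59 kb). Chad encodes chondroadherin, and neither deficient list had the peak that both controls had at its gene end. The opposite held for 2 genes, Pcolce2 and the lubricin gene Prg4 (0, 0.996, 2.92 and 1.41 kb), and Col2a1, the main cartilage collagen, had 11.6, 13.1, 11.8 and 11.8 kb.

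Of 29 chondrogenic regulators, 19 were covered by less and 7 by more, with a median difference of -0.559 kb and again 0 of 10000 random lists as low. Sox5 and Sox6, the SOX partners of Sox9 in chondrocytes, had the largest differences of the list, with 28.03, 41.5, 26.8 and 20.3 kb over Sox5 and 25.6, 52.4, 32.6 and 21.8 kb over Sox6. Sox9, Sox5, Maf and all 3 Runx genes were covered by less in each deficient list than in each control, with 20.8, 26.0, 17.2 and 12.4 kb over Runx1. For Sox9 the margin was very small between the E11.5 control (peaks of 5828 and 1972 bp) and the list labelled Sox9null (885, 5528 and 1351 bp). The latter lacked the middle of the gene, so the Sox9 value does not show less marking around the gene. Runx3 had a peak at a gene end in both controls and in neither deficient list. Arid5b (19.5, 33.8, 36.2 and 26.8 kb) and Trps1 (23.1, 27.4, 25.4 and 28.3 kb) had the largest gains. The regulator difference too rested on the E12.5 control, without which the median was 0 kb (percentile 4.46). With the upper 50% of each list by score, Chad, Mia and Runx2 were covered by more in the deficient lists.

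**Figure D2:**
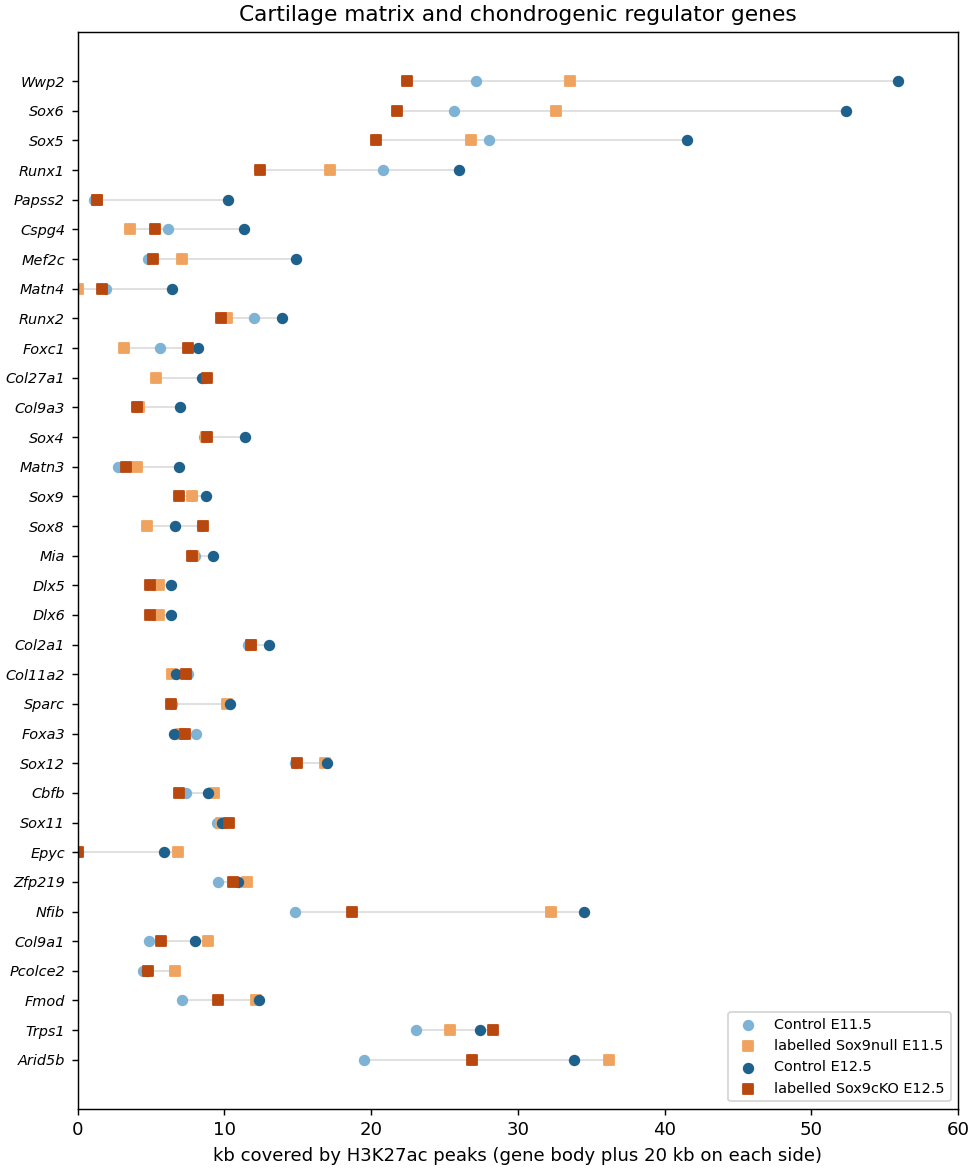
Kb covered by H3K27ac peaks (horizontal axis) over the 34 cartilage matrix and chondrogenic regulator genes that reached 6 kb in at least 1 list, one point per list (circles for controls, squares for Sox9-deficient lists). The E12.5 control stands to the right of the other lists for Wwp2 (55.9 kb), Sox6 (52.4 kb) and Sox5 (41.5 kb).

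Among genes of BMP signalling and joint formation, 16 of 28 were covered by less and 12 by more in the deficient lists, with a median difference of -0.175 kb (percentile 0.33). The BMP receptor gene Bmpr1b had 2.71, 10.3, 2.59 and 4.43 kb and the BMP antagonist gene Nog 2.004, 5.98, 2.07 and 1.89 kb, while Gdf5, a marker of the forming joint, had 8.97, 8.33, 12.1 and 10.6 kb. This difference too rested on single lists: the median was 0.66 kb (percentile 95.6) without the E12.5 control, and -0.268 kb (percentile 6.24) without the list labelled Sox9cKO. It was 0.0303 kb (percentile 30.6) with the upper 50% of each list, and within the central 95% of random lists with 5 or 100 kb on each side. Skeletal muscle markers had a median difference of 0.593 kb (percentile 100), with 13 of 21 covered by more and 4 by less, including Chrna1 (11.9, 14.9, 15.7 and 15.5 kb). The muscle median was 0 kb with the upper 50% of each list and without the E12.5 control or the list labelled Sox9cKO, 0.304 kb (percentile 93.7) without the list labelled Sox9null, and 0.234 kb (percentile 75.9) with 100 kb on each side. Erythroid and macrophage markers had a median difference of 0.556 kb (percentile 100), with 17 of 22 covered by more and 3 by less, including the erythropoietin receptor gene Epor (2.09, 1.59, 1.95 and 4.56 kb). Their median was 0 kb (percentile 58.1) without the list labelled Sox9cKO.

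Limb patterning genes had a median difference of 0.120 kb (percentile 8.62), with 22 of 38 covered by more and 15 by less, and of -0.467 kb (percentile 0.01) when covered length was scaled to the total of each list. The HoxA and HoxD genes of this list share broad peaks, which the random lists, drawn gene by gene, do not allow for. The homeobox gene Prrx2 had 30.1, 40.8, 44.7 and 40.5 kb, Tbx4, a hindlimb regulator, 29.7, 34.4, 38.1 and 31.9 kb, and Gli3, a hedgehog effector, 14.7, 28.6, 19.6 and 16.5 kb. The median difference was 0.0253 kb (percentile 14.6, and -0.0923 kb after scaling) for condensation and adhesion genes, in which Vcan had 5.56, 17.6, 9.25 and 8.85 kb. It was low with the same number of top peaks (-0.0738 kb, percentile 2.23) and with 100 kb on each side (-0.347 kb, percentile 0.5). The median was -0.0145 kb (percentile 3.83) for growth plate genes, in which Fgfr2 had 10.7, 29.5, 16.7 and 10.3 kb. Endothelial markers had a median difference of 0 kb (percentile 23.2), ectoderm markers of 0.146 kb (percentile 83.5), tendon and connective tissue markers of 0.074 kb (percentile 29.9) and nerve and glia markers of 0.0005 kb (percentile 78.4). Housekeeping genes had a median difference of 0.22 kb (percentile 56.5) and genes of inactive tissues of 0 kb (percentile 44.5). The tendon median went from -1.85 kb without the E11.5 control to 1.04 kb without the E12.5 control, and the limb patterning, condensation, growth plate, endothelial and ectoderm lists also left the central 95% of random lists when 1 of the 4 lists was left out.

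Over all genes, 1063 of 16659 with any peak (6.38%) were covered by less in each deficient list than in each control, and 2678 (16.1%) by more. Chance order would give 16.7% each way without ties, and less with them, since a gene covered in a single list cannot count. The other pairings gave 596 and 3607 genes for E11.5 and E12.5 by label. They gave 4593 for the E11.5 control with the list labelled Sox9cKO and 3408 for the other pair. After scaling to the total of each list the genes covered less in both Sox9-deficient lists than in both controls numbered 1018, against 1556 covered more. Among genes covered by less in each deficient list than in each control, the largest losses included Sox5, Nav2 (25.3, 40.6, 23.3 and 20.7 kb), Slc39a11, the neighbour of Sox9 (17.4, 19.7, 7.01 and 12.52 kb), Runx1, Magi1, Chst11, a chondroitin sulphotransferase (10.6, 18.3, 8.48 and 8.77 kb), Mindy4, Arhgap10 and Rbpjl. Among those covered by more in each, the 10 largest gains were at the proprotein convertase gene Pcsk6 (12.55, 13.98, 24.5 and 23.3 kb), the myosin light chain kinase gene Mylk, Gse1, Fmn1, Plxna4 (14.4, 18.6, 23.2 and 23.5 kb), Celf4, Itga9, the retinoid receptor gene Rxra (16.8, 23.1, 25.8 and 25.8 kb), Spock1 and Stox2, of which Fmn1 and Itga9 turned to less with the upper 50% of each list. A peak near a gene end was present in both controls and neither deficient list for 41 genes, including Chad, Runx3 and the basal keratin gene Krt5, and the reverse held for 28 genes.

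The 4 lists merged into 49367 regions, of which 19792 (40.1%) were marked in all 4. Regions in both controls and neither deficient list numbered 809, against 570 in both deficient lists and neither control. Peaks in these regions scored low. In the control regions the median score was 67.7 at E11.5 and 88.6 at E12.5, against 162.09 and 240.03 for all peaks of these lists. In the deficient regions it was 68.9 (labelled Sox9null) and 80.2 (labelled Sox9cKO), against 226.35 and 196.26. The lowest score in any list was 50.01, so many of these regions lie near the calling threshold. With the same number of top peaks from each list the direction turned, to 456 and 585, and with the upper 50% of each list the counts were 210 and 84. Pairing the stages by label gave 312 regions for E11.5 and 972 for E12.5. The third pairing gave 3186 regions shared only by the E11.5 control and the list labelled Sox9cKO with 1819 shared only by the E12.5 control and the list labelled Sox9null, which is the pairing by stage in the deposited names.

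**Figure D3:**
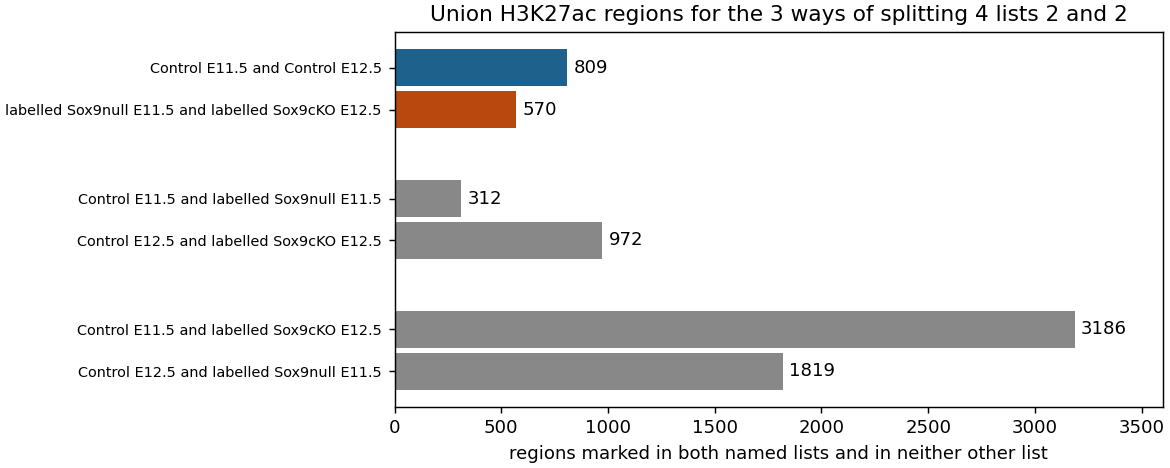
Number of merged H3K27ac regions (horizontal axis) marked in both of the named lists and in neither other list, for the 3 ways to split the 4 lists into pairs. The genotype pairs have 809 and 570 regions, and the pairs that cross the labelled stages have 3186 and 1819.

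From E11.5 to E12.5 in controls, cartilage and tendon genes were covered by more H3K27ac. This comparison was meant to address the normal course of acetylation as limb mesenchyme forms cartilage, but the controls also differed in peak width (1141 and 1707 bp) and in coverage of the forelimb gene Tbx5, and stage was not separated from these. Of 30 cartilage matrix genes, 22 were covered by more and 7 by less at E12.5, with a median difference of 1.12 kb that 0 of 10000 random lists reached, and of 0.316 kb (percentile 100) after scaling. Coverage went from 1.11 to 10.3 kb over Papss2, from 27.1 to 55.9 kb over Wwp2, from 2.13 to 5.79 kb over the link protein gene Hapln1, from 2.76 to 6.91 kb over Matn3 and from 0.465 to 4.67 kb over Cnmd, which encodes chondromodulin. No cartilage gene gained a peak near a gene end, and Cnmd, Snorc and Itih5 lost one. Of 29 regulators, 20 were covered by more and 5 by less (median 1.17 kb, percentile 99.3, but -0.382 kb, percentile 88.4, after scaling), with 14.8 and 34.5 kb over Nfib, 4.82 and 14.9 kb over Mef2c, and a peak at the chondrogenic homeobox gene Nkx3-2 at E12.5 alone.

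Tendon and connective tissue markers were covered by more in 13 of 16 genes (median 2.73 kb, percentile 99.98, and 1.251 kb after scaling). The small proteoglycan genes Kera (0 and 14.8 kb), Lum (2.14 and 10.8 kb) and Dcn (2.18 and 8.28 kb) lie side by side on chromosome 10 with Epyc (0 and 5.91 kb), so that these values share part of their peaks; Lum and Dcn were chosen here after their values were seen. Col12a1 had 2.87 and 9.47 kb. BMP and joint genes were covered by more in 22 of 28 (median 1.36 kb, percentile 99.8, -0.337 kb, percentile 97.6, after scaling, and 0.672 kb, percentile 94.5, with 5 kb on each side), with 24.1 and 35.2 kb over Smad7 and 2.71 and 10.3 kb over Bmpr1b, whereas Gdf6 had 2.31 and 0 kb. The median was 0.934 kb (percentile 96.1, and 99.9 after scaling) for condensation genes, with 1.11 and 5.52 kb over Tnc and 13.0 and 19.5 kb over Col1a2. It was 0.534 kb (percentile 97.3, and -0.594 kb, percentile 42.3, after scaling) for growth plate genes, in which Pthlh had a peak at E12.5 alone.

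Limb patterning genes, whose HoxA and HoxD members share peaks, were covered by more in 19 and by less in 17 of 38 (median 0.039 kb, percentile 0.37, and -3.68 kb after scaling). Their median lay within the central 95% of random lists with the upper 50% of each list (0.413 kb, percentile 20.5) and with 100 kb on each side (1.10 kb, percentile 33.2). Tbx5, the forelimb regulator, had 31.7 kb at E11.5 and 3.76 kb at E12.5, and Sall3 had 12.2 and 3.19 kb, while Gli3 had 14.7 and 28.6 kb. Endothelial markers (median -0.465 kb, percentile 0.05) were covered by less in 11 of 20, with 2.55 and 0 kb over Tie1, and erythroid and macrophage markers (median -0.093 kb, percentile 1.04) in 13 of 22, with 6.34 and 0 kb over Tal1. Ectoderm markers were covered by more in 13 of 20 (median 0.458 kb, percentile 99.5, and 0 kb after scaling), with 3.21 and 5.92 kb over the epidermal regulator Trp63. Each of these 3 medians was 0 kb with the upper 50% of each list. The muscle, nerve and inactive-tissue medians were 0 kb, with 28.4 and 44.1 kb over Tnnt3 and 2.31 and 0 kb over Pax3, and the housekeeping median was -0.306 kb (percentile 0.96). The housekeeping median did not stay below the central 95%, with percentile 3.58 for the upper 50%, 2.97 for the same number of top peaks, 10.1 with 5 kb on each side (0.031 kb) and 34.8 with 100 kb (0.692 kb). The muscle median was -0.784 kb after scaling. The E12.5 control covered 1.28-fold more of the genome than the E11.5 control (log2 0.36). A peak near a gene end was lost for 1055 genes and gained for 271. Of the E11.5 control peaks, 72.0% (Wilson 95% interval 71.5 to 72.5%) were overlapped by the E12.5 control.

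**Figure D4:**
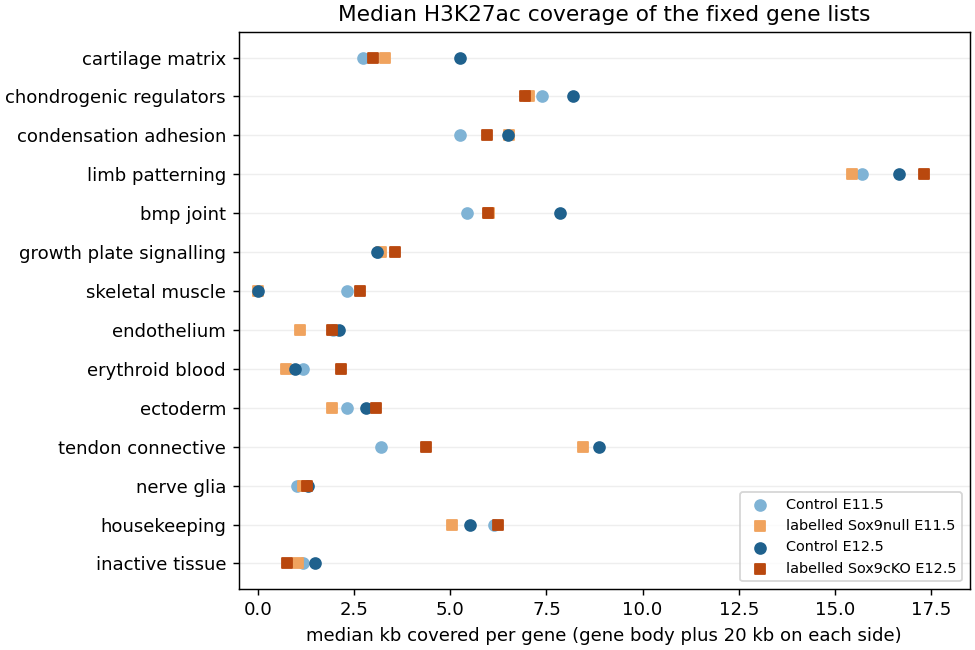
Median kb covered by H3K27ac peaks per gene (horizontal axis) for the 14 fixed gene lists, one point per list (circles for controls, squares for Sox9-deficient lists). The tendon list has 8.88 kb in the E12.5 control and 8.46 kb in the list labelled Sox9null, against 3.202 and 4.36 kb in the other 2.

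At E12.5 by label, the list labelled Sox9cKO had less H3K27ac than the control over cartilage, regulator, BMP and tendon genes. Cartilage genes had a median difference of -1.44 kb (0 of 10000 random lists as low; 20 of 30 by less, 9 by more), with 55.9 and 22.5 kb over Wwp2 and 10.3 and 1.32 kb over Papss2 in the control and deficient lists. Regulators had -1.43 kb (percentile 0), with 52.4 and 21.8 kb over Sox6, BMP and joint genes -1.01 kb (percentile 0), growth plate genes -0.308 kb (percentile 0.36; 0 kb after scaling) and tendon genes -2.24 kb (percentile 0), with 14.8 and 1.07 kb over Kera. Erythroid markers had 1.10 kb (percentile 100; 17 of 22 by more), with 0 and 5.54 kb over Tal1, and muscle markers 0.678 kb (percentile 99.7), with 0 and 6.37 kb over Lbx1, a gene of migrating muscle precursors. Endothelial markers had 0.431 kb (percentile 97.52), and Tbx5 had 3.76 and 32.6 kb. The growth plate, muscle and endothelial medians were 0 kb with the upper 50% of each list, and the erythroid median was 0 kb with 5 kb on each side. At E11.5 by label, 5 cartilage genes (Snorc, Matn4, Chad, Matn3 and Cnmd) had a peak near a gene end in the control alone and 0 in the deficient list alone. The list labelled Sox9null differed from the control by a median of 0.087 kb (percentile 76.0) over cartilage genes, which turned to less after scaling and with 100 kb on each side (-0.869 kb, percentile 1.24), and of 0 kb (percentile 26.98) over regulators. Tendon genes had 2.12 kb (percentile 100), with 0 and 13.8 kb over Kera, endothelial markers -0.52 kb (percentile 0.25; 0 kb with the upper 50% of each list), and Tbx5 31.7 and 0 kb. Peaks near gene ends were lost for 1282 genes and gained for 186 at E11.5. They were lost for 226 and gained for 1195 at E12.5. The list labelled Sox9null overlapped 67.8% of the E11.5 control peaks (67.3 to 68.3%) and the list labelled Sox9cKO 75.2% of the E12.5 control peaks (74.8 to 75.7%).

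With the assignment in the deposited names, the cartilage genes differed less at E12.5, and the differences at E12.5 in blood, muscle and endothelial markers were gone. The list labelled Sox9null against the E12.5 control gave medians of -0.46 kb (percentile 0.29; 21 of 30 by less, 6 by more) for cartilage genes, -0.855 kb (percentile 0.175) for regulators, -0.682 kb (percentile 0.91) for BMP and joint genes, -0.894 kb (percentile 1.29) for condensation genes, -0.648 kb (percentile 0.05) for ectoderm markers, -0.397 kb (percentile 24.7) for tendon genes and -0.186 kb (percentile 9.87) for growth plate genes. Erythroid (percentile 50.9), muscle (50.3) and endothelial markers (55.8) had medians of 0 kb. Papss2 had 10.3 and 1.33 kb, Sox6 52.4 and 32.6 kb, Wwp2 55.9 and 33.5 kb, and Kera 14.8 and 13.8 kb. The list labelled Sox9cKO against the E11.5 control gave 0.0205 kb (percentile 6.22) for cartilage genes, 0 kb (percentile 0.28) for regulators, 0.869 kb (17 of 22 by more) for erythroid markers, 0.820 kb (percentile 99.9) for ectoderm markers, 0.670 kb (percentile 85.5) for tendon genes and 0.454 kb (percentile 90.1) for endothelial markers, with 31.7 and 32.6 kb over Tbx5. Peaks near gene ends were then lost for 366 genes and gained for 551 at E11.5. They were lost for 542 and gained for 230 at E12.5. Overlaps were 78.0% (77.6 to 78.4%) of the E11.5 control peaks and 75.8% (75.3 to 76.2%) of the E12.5 control peaks, against at most 7.60% for lists shifted along the chromosomes.

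Between the 2 deficient lists, the list labelled Sox9cKO had more H3K27ac over blood, endothelial and ectoderm markers than the list labelled Sox9null, and less over tendon genes. Medians were 1.09 kb (percentile 100) for erythroid and macrophage markers, 0.779 kb (percentile 99.3) for endothelial, 0.833 kb (percentile 99.1) for ectoderm and -0.481 kb (percentile 0.13) for tendon markers, with the signs opposite if the lists are exchanged. Cartilage genes had a median of -0.0255 kb (percentile 0.355; 16 of 30 by less, 12 by more), with 33.5 and 22.5 kb over Wwp2 and 6.85 and 0 kb over Epyc, and regulators had a median of 0 kb (percentile 20.1), with 32.3 and 18.7 kb over Nfib. The regulator median was low with the same number of top peaks (-0.095 kb, percentile 1.82), with 5 kb on each side (-0.107 kb, percentile 0.205) and after scaling (-0.0115 kb, percentile 0.64). Limb patterning genes had 0.972 kb (percentile 92.1), with 0 and 32.6 kb over Tbx5 and 8.72 and 18.6 kb over Meis2, a gene of the proximal limb. A peak near a gene end was present in the list labelled Sox9cKO alone for 1411 genes and in the list labelled Sox9null alone for 130. With the upper 50% of each list, the cartilage and endothelial medians were 0 kb, and the erythroid and ectoderm medians lay within the central 95% of random lists.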

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

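The tests of peak width, of the E12.5 control alone, of the number of peaks behind the cartilage genes and of other cell types were chosen only after the result was seen; the others were set in advance.

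For 8 gene lists the deficient minus control median had opposite signs at the 2 stages by label, and the difference was not tested. The E11.5 list is also the Sox9null list and the E12.5 list the Sox9cKO list, so stage and kind of deficiency cannot be told apart. The E12.5 minus E11.5 difference of these medians was -1.53 kb for cartilage matrix genes, -0.829 kb for condensation genes, -1.35 kb for BMP and joint genes, -0.394 kb for growth plate genes and -4.36 kb for tendon genes. It was 0.951 kb for endothelial markers, 1.12 kb for erythroid and macrophage markers and 0.835 kb for housekeeping genes. With the lists exchanged, 6 of the 8 still had opposite signs, the endothelial and erythroid lists being the exceptions. After scaling to the total of each list, the cartilage, condensation, BMP and growth plate medians at E11.5 by label turned to less.

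Each deficient list shared more stage-specific peaks with the control of the other labelled stage: the list labelled Sox9null E11.5 overlapped 41.2% of the E12.5 control peaks missing from the E11.5 control and 14.1% of the E11.5 control peaks missing from the E12.5 control, and the list labelled Sox9cKO E12.5 29.5% and 44.1%. A lag of both deficient limb buds would need both lists to favour peaks of the E11.5 control. In the list labelled E11.5 the share of E12.5 control peaks was instead higher by 27.1 points. This cannot decide on a lag, because the 2 controls also differed in peak width and Tbx5 coverage, and stage was not separated from these. The lists may be exchanged relative to their titles, as the deposited names have them: the difference between the 2 lists in this preference was -41.7 points, below 0 on 19 of 19 autosomes (-46.6 to -35.5). This difference restates the shares above. The autosomes come from the same libraries and are not replicates, so any property of a whole library could give the same sign on all of them. A shared library batch of the lists with wide peaks (E12.5 control and labelled Sox9null) cannot be told apart from an exchange, since 6 of 14 gene lists were outside the central 95% of random lists in that split and 5 in the highest other split. A different share of fore and hind limbs was not tested, although Tbx5 followed the same pairs (31.7 and 32.6 kb against 3.76 and 0 kb). The hindlimb gene Tbx4 went the other way on unscaled covered length (29.7 and 31.9 kb against 34.4 and 38.1 kb), a smaller difference that may not hold after scaling.

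Cartilage and regulator genes were covered by less in the deficient lists. Fewer or weaker peaks in the deficient libraries were examined with the same number of top peaks from each list, where the cartilage genes stayed at percentile 0 (median -0.338 kb). This cannot decide the question, because a shortage over the whole genome would lower the random lists too, and peak width was not made equal. The deficient lists together covered 1.01-fold the length of the controls. A larger share of all other cell types would put all 5 such lists high, and 3 of 5 (endothelium, ectoderm, nerve) lay at or below percentile 90. This cannot decide the question, because ectoderm (12 genes by more, 7 by less) and nerve markers (8 by more, 2 by less) still leaned to more. Endothelial markers had 9 genes each way. Muscle and blood markers lay at percentile 100, so a larger share of other cell types stays open. For the cartilage genes the difference may come from the E12.5 control library alone, since without it the cartilage list lay at percentile 32.4. The regulator list lay at percentile 4.46 without that library. The loss of Sox9, which the design names, stays open and untested, as there was no second E12.5 control.

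Regions in both controls and neither deficient list outnumbered the reverse by a ratio of 1.42. Median scores of the peaks in both kinds of region were far below those of all peaks in each list, as given above. With the same number of top peaks from each list the ratio was 0.78, whereas with the upper 50% of each list the excess was kept (210 against 84). Fewer or weaker peaks in the deficient libraries cannot be told apart from a loss of acetylation at Sox9-dependent elements, because the ratio lay outside both ranges set in advance and only 3 splits of 4 lists exist.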

How the results depend on the processing

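Leaving out 1 list in turn, and the coverage of Sox9 in stricter lists, were chosen only after the result was seen; the other settings were set in advance. With autosomes alone, gene-end windows of 2500 bp, peaks within 1000 bp merged, or regions within 1000 bp merged, all the main counted results stayed within a ratio of 1.5 and kept their direction. No paired analysis was possible because each group had 1 library and the labels give no embryo or litter. The SOX motif search was not run, as no genome sequence was used here. Pairs of lists below are in the order E11.5 control by labelled Sox9null, E12.5 control by labelled Sox9cKO, E11.5 control by E12.5 control, labelled Sox9null by labelled Sox9cKO, E11.5 control by labelled Sox9cKO, E12.5 control by labelled Sox9null. For every result below that did not hold, the cause was not tested.

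The upper 50% of each list by score left 18023 peaks in the E11.5 control, 14210 in the list labelled Sox9null, 16412 in the E12.5 control and 18470 in the list labelled Sox9cKO. Overlaps were 73.4, 85.9, 79.4, 91.8, 91.7 and 82.1%. Regions numbered 210 in the controls alone, 84 in the deficient lists alone, 35 for E11.5 by label, 289 for E12.5 by label and 632 for the E12.5 control with the list labelled Sox9null. Gene ends marked in the controls alone were 22 and in the deficient lists alone 18. At E11.5 by label 1977 gene ends were lost and 120 gained, at E12.5 by label 141 were lost, and 71 were marked in the list labelled Sox9null but not in that labelled Sox9cKO. The cartilage median between the deficient lists was 0 kb. Deficient minus control differences turned for genes including Fmn1 (-1.46 kb), Itga9 (-1.08 kb), Chad (0.081 kb), Mia (0.171 kb), Runx2 (0.381 kb), Tbx2 (-0.771 kb), Enpp2 (0.0345 kb), Spp1 (-0.0055 kb), Polr2a (-0.557 kb) and Psma1 (0.119 kb). Sox9 was covered over 34.6% in the list labelled Sox9null.

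An overlap of at least 0.5 of both peaks gave 51.8, 64.4, 53.6, 72.5, 65.9 and 69.3%, and the Jaccard index of covered bp was 55.5, 56.2, 53.5, 58.4, 61.8 and 66.9%. With the same number of top peaks from each list, overlaps were 78.1% (E11.5 control by labelled Sox9null), 78.5% (between the controls), 76.8% (between the deficient lists), 83.5% (E11.5 control by labelled Sox9cKO) and 82.9% (E12.5 control by labelled Sox9null). Regions numbered 456 in the controls alone, 463 for E12.5 by label and 1947 for the E11.5 control with the list labelled Sox9cKO. The regulator median between the deficient lists was -0.095 kb (percentile 1.82), and Dcx (0.585 kb) turned.

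With the deficient lists exchanged, overlaps were 78.0% at E11.5, 75.8% at E12.5, 66.7% between the deficient lists, and 67.8% and 75.2% across stages. Regions numbered 3186 for E11.5, 1819 for E12.5, and 312 and 972 across stages. Gene ends lost and gained were 366 and 551 at E11.5, 542 and 230 at E12.5, and 1411 and 130 between the deficient lists. The regulator median at E11.5 stayed at 0 kb, but its percentile went from 26.98 by label to 0.28. Between the deficient lists the medians turned by construction, to 0.0255 kb for cartilage, 0.086 kb for BMP and joint, -0.779 kb for endothelial, -1.09 kb for erythroid, -0.833 kb for ectoderm and 0.481 kb for tendon genes.

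Regions covered over at least 0.5 of their length numbered 3498 for the E12.5 control with the list labelled Sox9null. A peak over the end base itself was gained in 48 genes between controls and deficient lists, in 360 at E11.5 by label and in 421 between the controls. With 5 kb on each side, the medians between the deficient lists were 0 kb for cartilage genes and -0.107 kb (percentile 0.205) for regulators, and Fn1 (-0.023 kb) and Psma1 (0.058 kb) turned. With 100 kb, the cartilage median was -0.869 kb (percentile 1.24) at E11.5 by label and 0.715 kb between the deficient lists, and Ucma (1.09 kb) turned. Scaled to the total of each list, 1556 genes were covered by more in both deficient lists, and the regulator medians were -0.382 kb between the controls and -0.0115 kb (percentile 0.64) between the deficient lists.

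Leaving out 1 list at a time eases the requirement by construction. Regions in the controls alone went from 1602 to 6020 and in the deficient lists alone from 1428 to 6559. Gene ends in the controls alone went from 90 to 405 and in the deficient lists alone from 52 to 416. Genes covered by less went from 2296 to 4995 and by more from 4371 to 8285. The cartilage median went from -1.31 to 0.073 kb and the regulator median from -1.09 to 0 kb.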

Other observations

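The test of the stretch inside Sox9 was chosen only after the result was seen, as were Meis1, Alx4 and Pitx1 among the genes named here and the pairing of lists in the next paragraph. The broadest peak of each list covered the HoxA cluster, with 53842 bp in the E11.5 control, 61680 bp in the E12.5 control, 54500 bp in the list labelled Sox9null and 54451 bp in the list labelled Sox9cKO. The HoxD cluster came next, with 36286, 52993, 47492 and 39644 bp in the same order. HoxC and Lmx1b, which specifies dorsal limb, were among the 10 broadest peaks of all 4 lists. Peaks over Tbx5 and Tbx15 were among the 10 broadest in the E11.5 control and the list labelled Sox9cKO alone. Dnm3 had 3 of the 10 broadest peaks in the E12.5 control and 2 in the list labelled Sox9null.

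The E11.5 control and the list labelled Sox9cKO shared marking that the other pair lacked, with 614 genes marked at an end in that pair alone against 44 in the E12.5 control and the list labelled Sox9null alone. The first pair also had more genes marked at an end in all (12446 and 12631) than the E12.5 control (11662) and the list labelled Sox9null (11350). Beside Tbx5, the genes marked in the E11.5 control and the list labelled Sox9cKO included the muscle precursor genes Lbx1, Myf6 and Msc, the endothelial genes Tie1 and Sox18, the blood regulator Tal1, the apical ridge gene Sp8 and the joint gene Gdf6. The patterning genes Meis1 (15.4, 19.04, 10.6 and 10.4 kb in the E11.5 control, labelled Sox9cKO, E12.5 control and labelled Sox9null) and Alx4 (12.2, 12.2, 7.001 and 5.07 kb) followed the same pairs. Over the E12.5 control and the list labelled Sox9null, the tendon genes were covered by more, with a median difference of 1.95 kb (percentile 100), and the cartilage genes by 0.868 kb (percentile 100), while erythroid and macrophage markers had -0.743 kb (percentile 0.01). The muscle (-0.197 kb, percentile 6.0), endothelial (-0.2965 kb, percentile 6.7) and ectoderm medians (0.00675 kb, percentile 87.05) lay within the central 95% of random lists. BMP and joint genes had 0.689 kb (percentile 99.96). The muscle, endothelial, ectoderm and joint genes named above thus do not stand for their lists. Tbx4 and Pitx1, which mark the hindlimb, were covered by less in the E11.5 control and the list labelled Sox9cKO (29.7 and 31.9 kb over Tbx4, 16.0 and 17.5 kb over Pitx1) than in the E12.5 control and the list labelled Sox9null (34.4 and 38.1 kb, 18.3 and 17.9 kb). These lengths were not scaled to the total of each list. Totals were 52.0 and 60.4 Mb for the first pair and 66.7 and 59.7 Mb for the second. The Pitx1 difference was small beside these totals, so neither gene is read as showing the limb type.

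Peaks found in 1 list alone numbered 5211 in the E11.5 control, 1610 in the list labelled Sox9null, 4301 in the E12.5 control and 5989 in the list labelled Sox9cKO. The highest-scored of them lay 22732 bp from Onecut1 in the E11.5 control (score 309.01), 48904 bp from Wdr11 in the list labelled Sox9null (288.13), 54382 bp from Tars in the E12.5 control (654.24) and over Sfn in the list labelled Sox9cKO (351.12). Others of the E12.5 control lay over Stk4 and Lrrc8d.

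The stretch inside Sox9 covered in both controls and in neither deficient list spans 1558 bp (chromosome 11, 112784128 to 112785685), with peaks of both deficient lists on either side. If sequence is missing from both Sox9-deficient alleles, it should stand out among all such stretches with deficient peaks within 3 kb on both sides, and it ranked 1 of 452 by length, ahead of 1156 bp on chromosome 2. The sequence missing from both Sox9-deficient alleles is a hypothesis that may hold under either assignment of the lists. Reads over the stretch were not analysed here.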
